A study of Homo sapiens with 12 samples.

How the data were processed

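Gene expression was measured with Affymetrix arrays in leukaemia cells of 3 donors with chronic lymphocytic leukaemia (CLL). The cells of each donor received 4 treatments, so that there were 12 arrays, 3 per treatment. Per the labels' protocols, CLL cells were enriched as B cells, kept for 48 h in vehicle or 0.5 µM lenalidomide, and then for 72 h in vehicle or lenalidomide again, to which IL-21 (100 ng/ml) was added or not. Total RNA was checked on a Bioanalyzer and labelled with biotin with an Enzo kit, per the labels' protocols. The treatment and the donor number of each array come from the labels.

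The deposited value table holds log2 expression values per probe set, made by the submitters with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, quantile-normalises the arrays and summarises the probes of a set. The version of either tool is not given in the sources used here. The values ranged from 2.24 to 14.87, the range of the log2 scale, and were used without further normalisation. Mean array medians were 5.606 (vehicle), 5.601 (lenalidomide), 5.604 (IL-21) and 5.608 (lenalidomide plus IL-21). For arrays, their number limits the precision.

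The table holds 54675 probe sets, of which 41091 have 1 gene symbol, 1801 have several, 11721 have none and 62 are controls. Of those with 1 gene, 41037 were matched to the reference gene table through their Entrez identifier and 54 kept the symbol of the array annotation. Each of 19732 genes was represented by its probe set with the highest mean over all 12 arrays. A total of 8392 genes had several probe sets, and where the probe sets of a named changed gene differ in sign, the text says so. Other probe sets of a gene can differ from it in the size of a change. Genes with a mean under the 40th percentile of the probe sets with 1 gene (5.272) were left out as dim, which left 13195 genes. Probe sets with several genes or none were tested separately and name no gene. Y-linked genes, XIST and TSIX were left out of every named result, and some genes of the fixed lists were not analysed here.

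Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) in 1 model over all 12 arrays with the treatment and the donor as a fixed replicate block, which leaves 6 residual degrees of freedom (3.52 prior degrees of freedom). There were 5 comparisons of 2 treatments and 1 interaction, the effect of lenalidomide with IL-21 minus its effect without IL-21. P values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, with a threshold of 0.05, and are called adjusted p. All log2 changes are given with their standard error from this model, over n = 3 donors. The donor numbers pair the arrays because each number marks 1 donor. After removal of the treatment means, arrays of the same donor correlated at 0.56 to 0.847 (18 pairs) and arrays of different donors at -0.524 to -0.205 (36 pairs). Removing the means makes the deviations of the 3 donors sum to 0 in each treatment, which by itself pushes the values between donors below 0.

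A total of 34 gene lists were tested with limma's camera on the same genes and model, with a preset correlation between genes of 0.01 and a minimum of 5 measured members, adjusted over the lists of each comparison. For each list the number of members past the threshold is given over all genes tested and adjusted over the list alone. The call with a correlation estimated from the residuals is given beside it. The lists cover STAT3 feedback and early IL-21 targets, interferon-stimulated genes, plasma cell differentiation, B cell identity, B cell receptor signalling, pro-apoptotic BCL2 family genes, anti-apoptotic genes, death receptors with caspases and ligands, cytotoxic effector genes, the cereblon pathway with known responders to immunomodulatory drugs, co-stimulation and activation markers, MHC class II presentation, MHC class I presentation, NF-kappaB targets, cytokines and chemokines, homing and adhesion receptors, and cytokine receptors of the common gamma chain with the Janus kinases. The others cover cell cycle and proliferation, ribosome biogenesis with MYC targets, the unfolded protein response, heat shock with oxidative stress, p53 targets, glycolysis with hypoxia, oxidative phosphorylation, cholesterol and fatty acid synthesis, immediate early genes, cytosolic ribosomal proteins, and markers of T cells, NK cells, monocytes and macrophages, platelets, erythroid cells, dendritic cells, and nurse-like and stromal cells. One gene fixed as a member of these lists is not reported here.

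The model, the comparisons, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. Under that rule the text names, per comparison, the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05 and the same direction in all 3 donors. Where fewer than 10 genes passed, the 5 smallest p values in each direction are named as not passing. In every comparison IL21R, IL2RG, CRBN, IKZF1, IKZF3, IRF4, GZMB, SOCS3, PRDM1, STAT3 and BCL2L11 were looked up, and for each described list 2 to 4 members with the smallest p are named. Immunoglobulin variable segments, and HLA genes outside the lists, were not named.

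Alternatives were the model without the replicate block, the donor as a random effect, the block with an RNA quality covariate (the mean 3 prime minus 5 prime difference of the ACTB and GAPDH control probe sets), no filter and a filter at the 60th percentile, the mean over a gene's probe sets, the exclusion of probe sets whose names mark shared sequence, quantile normalisation of the values again, median centring of each array, eBayes without the trend or with its robust option, array weights, a fit of only the 2 treatments compared, a minimum change of 2-fold, and each donor left out in turn. Control probe sets for ribosomal RNA, poly-A spike-ins and hybridisation were compared between treatments by an exact two-sided sign-flip test over 3 donors, whose smallest possible p is 0.25. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 drew the figures.

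The scripts were tested on simulated data with the real genes' means and spreads, with known changes of 1.414, 2 and 4-fold. For lenalidomide versus vehicle 46.3, 89.6 and 100 % of the changed genes were recovered at these sizes, and for IL-21 versus vehicle 35.8, 92.5 and 100 %. Recovery was 41.8, 88.1 and 97.0 % for lenalidomide plus IL-21 versus vehicle, 31.3, 85.1 and 98.5 % for it versus IL-21, and 40.3, 83.6 and 98.5 % for it versus lenalidomide. The interaction recovered 8.96, 79.1 and 95.5 %. Of the genes called in the simulation, 3.38 to 7.65 % were false over the 6 comparisons. Its noise was independent between genes and equal in spread over the arrays, so these shares need not hold for the real calls.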

Results

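Expression of 13195 genes was compared between 4 treatments of CLL cells from 3 donors, with 1 array per donor and treatment. Lenalidomide is an immunomodulatory drug that binds cereblon, the substrate receptor of an E3 ubiquitin ligase. IL-21 is a cytokine that signals through IL21R and the common gamma chain to Janus kinases and STAT proteins. The treatments are called vehicle, lenalidomide, IL-21 and lenalidomide plus IL-21. The donor accounted for 57.2 % of the variance between arrays, the treatment for 28.6 % and the remainder for 14.2 %. Arrays of the same treatment correlated at 0.973 to 0.985 and arrays of the same donor at 0.981 to 0.992. Changes are differences on the log2 scale ± standard error with n = 3 donors. A gene rose or fell where limma's adjusted p was under 0.05, and every gene that passed changed in the same direction in 3 of 3 donors.

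The first comparison asked what lenalidomide changed without IL-21. TNFSF13B, which encodes the B cell survival factor BAFF, rose 8.84-fold (3.14 ± 0.40, adjusted p = 0.0182), and the cell surface genes CD59 (1.86 ± 0.18), CD274 (1.36 ± 0.27), which encodes PD-L1, and ICAM1 (1.30 ± 0.24) rose with it. The transcription factor KLF2 fell (-2.22 ± 0.32) to a level 4.66-fold lower, and the protocadherin PCDH9 fell by more (-2.43 ± 0.40). The surface receptors FCRL1 (-1.56 ± 0.27) and FCRL2 (-1.36 ± 0.26) and HLA-DOB, which limits peptide loading of MHC class II (-1.60 ± 0.19), also fell. Of the genes tested, 188 changed, 80 upward and 108 downward, of which 28 rose and 25 fell at least 2-fold. At an unadjusted p under 0.05 there were 2157 genes, against 660 by chance.

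The other large rises were in PLA2G4C (2.32 ± 0.39), NOD2, an intracellular sensor of bacterial cell wall fragments (2.00 ± 0.37), TRIP6 (1.88 ± 0.26), RAB13 (1.87 ± 0.27), the interferon-induced OAS3 (1.77 ± 0.29), SHTN1 (1.33 ± 0.21), B3GNT2 (1.27 ± 0.19) and the kinase STK3 (1.27 ± 0.25). The other large falls were in CPNE5 (-1.71 ± 0.33), TGFBI (-1.695 ± 0.28), ZCCHC18 (-1.62 ± 0.28), SLC15A2 (-1.42 ± 0.28), TOP6BL (-1.40 ± 0.21), SDK2 (-1.33 ± 0.21) and LFNG (-1.30 ± 0.23). Adjusted p values of these named genes lay between 0.0140 (CD59) and 0.0470 (CD274). Of these genes 6 had another probe set with a much smaller change: -0.222 for KLF2, 0.582 for CD274, -0.454 for HLA-DOB, -0.458 for FCRL2, -0.0412 for SDK2 and -0.0619 for LFNG. No gene of the drugs' own targets passed on the probe set used. CRBN, which encodes cereblon, differed by -0.19 ± 0.11, adjusted p = 0.417, and the transcription factors that cereblon recruits under the drug by 0.98 ± 0.27, adjusted p = 0.113 (IKZF1) and -0.22 ± 0.22, adjusted p = 0.696 (IKZF3). Over the 9 probe sets of IKZF1 the change ranged from 0.195 to 2.28. Only transcripts were measured, so these values do not bear on the proteins. The values were 0.16 ± 0.41 for IL21R, -0.032 ± 0.15 for IL2RG, 0.20 ± 0.42 for IRF4, -0.17 ± 0.21 for SOCS3, 0.034 ± 0.080 for PRDM1, 0.14 ± 0.26 for STAT3 and 0.44 ± 0.39 for BCL2L11. GZMB lay below the level tested in every comparison, with a mean of 4.79.

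Of 27 interferon-stimulated genes measured, 1 rose (OAS3), 0 fell and 26 did not pass, with 13 rising and 0 falling when adjusted over the list alone. Their median was 1.05, with values of 2.62 ± 0.58 for IFIT3, 2.44 ± 0.54 for IFI6 and 1.05 ± 0.25 for IFIH1. The interferon list had a camera adjusted p of 1.09e-11 and adjusted p = 0.492 with an estimated correlation. The p53 targets had a median of 0.39, and 2 of 17 rose, 0 fell and 15 did not pass, with 8 rising when adjusted over the list alone. RPS27L rose (0.66 ± 0.087), as did MDM2, the ubiquitin ligase of p53 (0.89 ± 0.15), and the cell cycle inhibitor CDKN1A had 1.66 ± 0.38, adjusted p = 0.0692. For the p53 list camera gave an adjusted p of 1.05e-06, but adjusted p = 0.348 with an estimated correlation. Of 18 co-stimulation and activation markers, 4 rose, 0 fell and 14 did not pass, against 6 rising when adjusted over the list alone. CD70 (1.17 ± 0.17) and TNFSF9 (0.63 ± 0.13), both ligands of the TNF family, rose besides CD274 and ICAM1, and the median was 0.41 (adjusted p = 5.42e-05, adjusted p = 0.348 with an estimated correlation). The NF-kappaB targets had a median of 0.42 with 1 rise (ICAM1) and 0 falls among 17, 2 rises when adjusted over the list alone, and a value of 1.74 ± 0.41, adjusted p = 0.0760 for IER3. The NF-kappaB list had a camera adjusted p of 0.00193 and adjusted p = 0.752 with an estimated correlation.

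B cell identity genes had a median of -0.36. Of 20 measured, 3 fell, 0 rose and 17 did not pass, with 5 falling when adjusted over the list alone, among them the transcription factor SPIB (-1.15 ± 0.20), FCRL1 and FCRL2. For the B cell identity list camera gave an adjusted p of 0.000117, but adjusted p = 0.109 with an estimated correlation. In MHC class II presentation 1 of 10 fell (HLA-DOB), 0 rose and 2 fell when adjusted over the list alone. CD74, the invariant chain, had -0.30 ± 0.092, adjusted p = 0.141, and the list median was -0.25. The MHC class II list had a camera adjusted p of 0.000117 and adjusted p = 0.458 with an estimated correlation. No member of the death receptors, caspases and ligands passed over all genes, of 12 measured, and 4 rose when adjusted over the list alone. Their median was 0.48, with 0.55 ± 0.15 for CASP6, 0.55 ± 0.15 for TNFRSF10B and 0.62 ± 0.18 for FAS. For the death receptor list camera gave an adjusted p of 0.0212, but adjusted p = 0.348 with an estimated correlation. Glycolysis and hypoxia genes had a median of 0.28 with 0 rises and 0 falls among 24 in limma and 0 when adjusted over the list alone, for example -0.45 ± 0.14 for NDRG1 and 0.36 ± 0.14 for PFKM. The glycolysis list had a camera adjusted p of 0.0212 and adjusted p = 0.873 with an estimated correlation. The median of each of these 8 lists had the same sign in 3 of 3 donors.

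The number of lenalidomide genes depended on the donors: limma called 0 genes without replicate 1 (2122 at an unadjusted p under 0.05), 215 without replicate 2 and 0 without replicate 3 (962), and 0 in the model without the replicate block (748). Of the 215 genes, 135 rose and 80 fell, and 87 were among the 188 of the full model. The death receptor list had an adjusted p of 0.0549 without replicate 3, and the glycolysis list 0.128 without replicate 1.

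The second comparison asked what IL-21 changed without lenalidomide. IL2RA, the alpha chain of the IL-2 receptor, rose 9.11-fold (3.19 ± 0.67, adjusted p = 0.0448), and HIF1A, the transcription factor of the hypoxia response, rose 8.29-fold (3.05 ± 0.32, adjusted p = 0.00466). Transcripts of the negative feedback genes of cytokine signalling SOCS1 (2.35 ± 0.27, adjusted p = 0.00582) and SOCS3 (1.06 ± 0.21, adjusted p = 0.0359) rose, together with STAT3 itself (1.41 ± 0.26, adjusted p = 0.0276) and the germinal centre factor BCL6 (2.27 ± 0.37, adjusted p = 0.0197). FCER2, which encodes CD23, fell (-2.15 ± 0.20, adjusted p = 0.00466), and the Ig transporter PIGR fell to a level 5.23-fold lower (-2.39 ± 0.33, adjusted p = 0.00963). In all 301 genes changed, 170 upward and 131 downward, of which 73 rose and 28 fell at least 2-fold. At an unadjusted p under 0.05 there were 2248 genes, against 660 by chance. The 28S ribosomal RNA control probe sets were also higher with IL-21 than with vehicle, by 1.13 ± 0.18 (SD, n = 3 donors). The 3 prime minus 5 prime difference was lower in 3 of 3 donors for both ACTB (-0.114 ± 0.0685) and GAPDH (-0.0308 ± 0.0266), and with the RNA quality covariate 14 genes passed, 11 of them among the 301.

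Among the other large rises were the glycolytic regulator PFKFB3 (2.60 ± 0.30), the glucose transporter SLC2A3 (2.10 ± 0.27), the potassium channel KCNN3 (2.00 ± 0.20), and the chemokine receptor CCR6 (1.99 ± 0.37). Next came KISS1R (1.90 ± 0.41), the tyrosine phosphatase PTPN1 (1.89 ± 0.20), PCED1B (1.87 ± 0.24) and CLDN23 (1.77 ± 0.27). The largest other falls were in FMOD (-2.35 ± 0.24), CKAP2 (-2.09 ± 0.27), KCNH8 (-2.06 ± 0.36), LOC339260 (-1.92 ± 0.21) and the kinetochore gene ZWINT (-1.79 ± 0.22). Falls in MAP2 (-1.73 ± 0.31), TNFRSF17, which encodes the receptor BCMA (-1.53 ± 0.32), ICAM2 (-1.48 ± 0.15), PLPP5 (-1.47 ± 0.19) and COL9A2 (-1.41 ± 0.17) were smaller. PRDM1, the plasma cell factor Blimp-1, rose (0.40 ± 0.080, adjusted p = 0.0356), with 0.221 to 1.29 over its 3 probe sets, and SOCS3 had 1.06 to 5.02 over its 3 probe sets. A much smaller change was found on another probe set of SOCS1 (0.0121), CKAP2 (-0.169), MAP2 (-0.487) and COL9A2 (-0.472). The receptor chains had 1.22 ± 0.41, adjusted p = 0.168 for IL21R and -0.66 ± 0.15, adjusted p = 0.0529 for IL2RG, and neither passed. The values for the remaining treatment genes, none of which passed, were -0.98 ± 0.42 for IRF4, 0.80 ± 0.27 for IKZF1, 0.25 ± 0.22 for IKZF3, 0.0040 ± 0.11 for CRBN and 0.57 ± 0.39 for BCL2L11.

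Of 12 measured STAT3 feedback genes and early IL-21 targets, 6 rose, 0 fell and 6 did not pass, and 9 rose when adjusted over the list alone. Besides SOCS1, SOCS3, STAT3, BCL6 and IL2RA the kinase PIM2 rose (1.44 ± 0.23), and the median was 1.14. For the IL-21 feedback list camera gave an adjusted p of 9.48e-08, but adjusted p = 0.539 with an estimated correlation. Cytokine receptors of the common gamma chain and Janus kinases had 4 rises and 0 falls among 14, with 6 rises and 1 fall when adjusted over the list alone. JAK3 (1.31 ± 0.16), IL2RB (1.22 ± 0.26) and IL15RA (0.55 ± 0.12) rose with IL2RA, while the list did not pass as a whole (median 0.15, camera adjusted p = 0.0542). Glycolysis and hypoxia genes had a median of 0.50, and 5 of 24 rose, 0 fell and 19 did not pass, with 7 rising when adjusted over the list alone. LDHA, lactate dehydrogenase A, rose by 1.59 ± 0.23, PGK1 by 0.93 ± 0.18 and PFKM by 0.80 ± 0.14. The glycolysis list had a camera adjusted p of 2.60e-07 and adjusted p = 0.539 with an estimated correlation. In the cell cycle list 2 of 21 fell, 0 rose and 19 did not pass, and 3 fell and 1 rose when adjusted over the list alone. The mitotic checkpoint kinase BUB1B (-1.196 ± 0.18) and ZWINT fell, and the median was -0.29. For the cell cycle list camera gave an adjusted p of 0.00120, but adjusted p = 0.539 with an estimated correlation. Of 13 MHC class I presentation genes, 1 rose and 0 fell, with 2 rising when adjusted over the list alone. The immunoproteasome subunit PSMB8 rose (0.63 ± 0.10), PSMB9 had 0.42 ± 0.12 and the median was 0.22. The MHC class I list had a camera adjusted p of 0.00164 and adjusted p = 0.539 with an estimated correlation.

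Camera also passed 4 further lists, in which limma called 0 rises and 0 falls over all genes. MHC class II presentation had a median of -0.17 over 10 genes, 3 falls when adjusted over the list alone and -0.62 ± 0.14 for HLA-DMB. For the MHC class II list camera gave an adjusted p of 0.0229, but adjusted p = 0.707 with an estimated correlation. For NF-kappaB targets the median was -0.38 over 17 genes, with 1 rise and 2 falls when adjusted over the list alone and -2.60 ± 0.60 for the chemokine CCL4. The NF-kappaB list had a camera adjusted p of 0.0270 and adjusted p = 0.724 with an estimated correlation. Oxidative phosphorylation had a median of 0.10 over 22 genes, 0 rises when adjusted over the list alone and 0.74 ± 0.19 for NDUFA9. For the oxidative phosphorylation list camera gave an adjusted p of 0.0270, but adjusted p = 0.724 with an estimated correlation. Cholesterol and fatty acid synthesis had a median of 0.22 over 15 genes, 0 rises when adjusted over the list alone, 0.75 ± 0.20 for IDI1 and 0.50 ± 0.17 for LSS. The cholesterol list had a camera adjusted p of 0.0113 and adjusted p = 0.724 with an estimated correlation. List medians had the same sign in 3 of 3 donors except for NF-kappaB targets (2 of 3).

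The number of IL-21 genes was 118 without replicate 1, 73 without replicate 2 and 0 in limma without replicate 3 (1252 at an unadjusted p under 0.05), and 9 without the replicate block. Adjusted p values of lists rose above 0.05 without replicate 1 for glycolysis (0.101), without replicate 2 for MHC class II (0.0573) and NF-kappaB targets (0.265), and without replicate 3 for NF-kappaB targets (0.0938), oxidative phosphorylation (0.0938) and cholesterol synthesis (0.0938).

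Cells given both drugs were compared with vehicle to describe the combined treatment. DEPP1 rose 16.9-fold (4.08 ± 0.41, adjusted p = 0.00197), the highest of the rises on the probe sets used, followed by the receptor chain IL13RA1 (3.26 ± 0.49) and HIF1A (3.17 ± 0.32). The inhibitory receptor LAG3 (3.06 ± 0.42, adjusted p = 0.00412), the cell cycle inhibitor CDKN1A (2.85 ± 0.38, adjusted p = 0.00412) and the death-promoting BID (2.83 ± 0.42, adjusted p = 0.00561) rose about as far. TNFRSF17 fell to a level 8.24-fold lower (-3.04 ± 0.32, adjusted p = 0.00205), and the kinase LCK fell too (-1.74 ± 0.14, adjusted p = 0.000872). In all 1078 genes changed, 499 upward and 579 downward, of which 179 rose and 73 fell at least 2-fold. At an unadjusted p under 0.05 there were 3090 genes, against 660 by chance. The 28S control probe sets were 2.36 ± 0.50 (SD, n = 3) higher, and the poly-A spike-in controls 0.44 ± 0.17 higher, than with vehicle, both in 3 of 3 donors.

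The other large rises were in F13A1 (3.08 ± 0.77), the tyrosine kinase FES (3.08 ± 0.62), IL4I1, a secreted amino acid oxidase (2.86 ± 0.43), STAG3 (2.74 ± 0.49), the mitochondrial superoxide dismutase SOD2 (2.71 ± 0.27) and SUSD1 (2.53 ± 0.39). Large falls were found in KMO, an enzyme of the kynurenine pathway (-2.97 ± 0.48), PCDH9 (-2.58 ± 0.40), CKAP2 (-2.15 ± 0.27), PIGR (-2.07 ± 0.33), CPNE5 (-1.98 ± 0.33), TOP6BL (-1.90 ± 0.21), FCRL2 (-1.88 ± 0.26), HLA-DOB (-1.79 ± 0.19), KCNH8 (-1.72 ± 0.36) and SOBP (-1.701 ± 0.24). IL21R rose with both drugs (1.61 ± 0.41, adjusted p = 0.0432), as did IKZF1 (1.32 ± 0.27, adjusted p = 0.0198), STAT3 (1.66 ± 0.26, adjusted p = 0.00634), SOCS3 (1.701 ± 0.21, adjusted p = 0.00369) and PRDM1 (0.52 ± 0.080, adjusted p = 0.00634). The 3 probe sets of SOCS3 ranged from 1.7 to 6.34, those of PRDM1 from 0.382 to 1.47 and the 9 of IKZF1 from 0.49 to 3.58. Smaller falls were found on another probe set of CKAP2 (-0.477), FCRL2 (-0.391) and HLA-DOB (-0.555). The pro-apoptotic BCL2L11 had 1.30 ± 0.39, adjusted p = 0.0729, positive in 2 of 3 donors, and IRF4 0.53 ± 0.42, IKZF3 0.46 ± 0.22, IL2RG -0.26 ± 0.15 and CRBN -0.10 ± 0.11 did not pass either. GZMB, below the level tested, had a mean of 3.98 ± 0.19 (SD, n = 3) with vehicle and 5.58 ± 1.8 with both drugs.

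**Figure D1:**
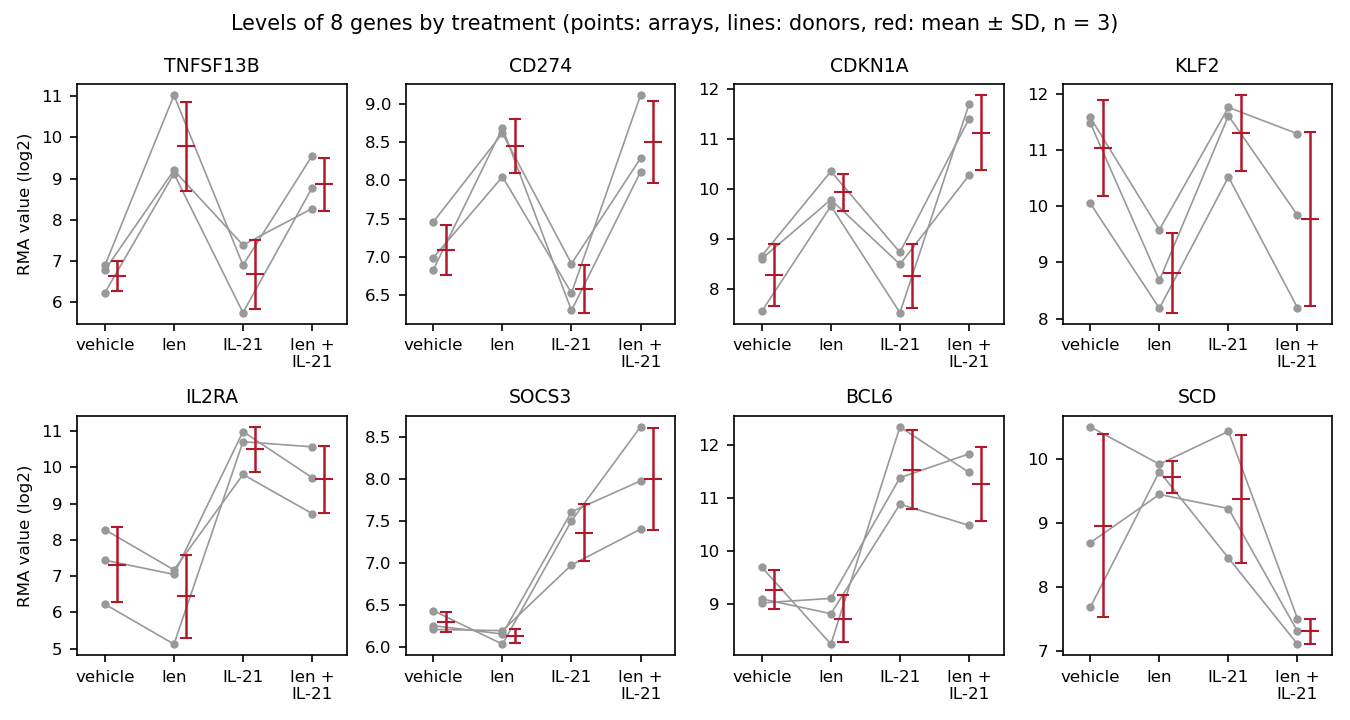
Expression (RMA log2 values, y axis) of 8 genes under the 4 treatments (x axis); points are arrays, grey lines join the arrays of a donor, and red marks give the mean ± SD (n = 3). TNFSF13B and CD274 are higher in both groups with lenalidomide, IL2RA, SOCS3 and BCL6 in both groups with IL-21, and KLF2 is lowest with lenalidomide alone.

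Of 12 STAT3 feedback genes and early IL-21 targets, 8 rose, 0 fell and 4 did not pass, with 11 rising when adjusted over the list alone and a median of 1.64. The AP-1 family factor BATF (1.94 ± 0.22), SOCS1 (1.98 ± 0.27) and PIM2 (1.60 ± 0.23) were among them. For the IL-21 feedback list camera gave an adjusted p of 8.11e-11, but adjusted p = 0.310 with an estimated correlation. In the p53 list 8 of 17 rose, 0 fell and 9 did not pass, with 11 rising when adjusted over the list alone, and the median was 0.59. The p53 list had a camera adjusted p of 9.53e-07 and adjusted p = 0.320 with an estimated correlation. Of 9 pro-apoptotic BCL2 family genes, 2 rose (BID and BMF, 0.97 ± 0.16) and 1 fell (HRK, -0.55 ± 0.094), against 4 and 1 when adjusted over the list alone (median 0.39, camera adjusted p = 0.00793, adjusted p = 0.310 with an estimated correlation). Of 12 death receptors, caspases and ligands, 5 rose and 1 fell, or 6 and 2 adjusted over the list alone. These rises included TNFRSF1A (1.02 ± 0.14), FAS (1.29 ± 0.18), TNFRSF10B (0.68 ± 0.15) and CASP6 (0.60 ± 0.15), and the median was 0.40. For the death receptor list camera gave an adjusted p of 0.0359, but adjusted p = 0.320 with an estimated correlation. Anti-apoptotic genes did not pass as a list (median 0.17, camera adjusted p = 0.0739), but MCL1 (0.65 ± 0.14), CFLAR (1.42 ± 0.30) and BCL2L2 (0.53 ± 0.12) rose, 3 of 9, or 4 adjusted over the list alone.

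Co-stimulation and activation markers had 6 rises and 0 falls among 18, and 8 and 2 when adjusted over the list alone. CD70 (1.25 ± 0.17), ICAM1 (1.45 ± 0.24), CD274 (1.41 ± 0.27) and TNFRSF14 (0.53 ± 0.090) rose, and the median was 0.36. The co-stimulation list had a camera adjusted p of 0.00537 and adjusted p = 0.377 with an estimated correlation. Common gamma chain receptors and Janus kinases had 4 rises and 0 falls among 14, or 6 and 1 adjusted over the list alone, with JAK3 at 1.89 ± 0.16, IL2RB at 1.68 ± 0.26 and a median of 0.31. For the gamma chain list camera gave an adjusted p of 0.0359, but adjusted p = 0.365 with an estimated correlation. Of 27 interferon-stimulated genes, 3 rose and 0 fell, the same as when adjusted over the list alone. All 3 are guanylate-binding proteins, GBP1 (1.73 ± 0.33), GBP5 (1.19 ± 0.29) and GBP4 (1.43 ± 0.38), and the median was 0.42. The interferon list had a camera adjusted p of 0.0145 and adjusted p = 0.726 with an estimated correlation. MHC class II presentation had 5 falls and 0 rises among 10, with 8 falls adjusted over the list alone, among them CD74 (-0.47 ± 0.092, with -0.928 to 0.0855 over 3 probe sets that differ in sign), HLA-DMB (-0.65 ± 0.14) and HLA-DOA (-0.76 ± 0.16), and a median of -0.47. For the MHC class II list camera gave an adjusted p of 4.80e-06, but adjusted p = 0.320 with an estimated correlation. Ribosome biogenesis and MYC targets had 1 rise (LDHA, 1.23 ± 0.23) and 3 falls among 18, unchanged in number when adjusted over the list alone. MYC itself (-1.501 ± 0.37), ODC1 (-1.03 ± 0.20) and FBL (-0.50 ± 0.11) fell, and the median was -0.21. The ribosome biogenesis list had a camera adjusted p of 0.0185 and adjusted p = 0.726 with an estimated correlation. Cholesterol and fatty acid synthesis had 4 falls and 0 rises among 15, or 6 and 1 adjusted over the list alone. The falls included INSIG1 (-1.15 ± 0.19), ACACA (-0.76 ± 0.15) and the desaturase SCD (-1.65 ± 0.43), and the median was -0.28, negative in 2 of 3 donors. For the cholesterol list camera gave an adjusted p of 0.0177, but adjusted p = 0.595 with an estimated correlation.

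Several lists that did not pass camera still held called genes. B cell identity had 5 falls and 0 rises among 20 (7 and 0 adjusted over the list alone, median -0.12, camera adjusted p = 0.0546), among them CD37 (-0.76 ± 0.10) and FCER2 (-1.496 ± 0.20). B cell receptor signalling had 3 rises and 2 falls among 16 (4 and 4 adjusted over the list alone, median -0.082, adjusted p = 0.797), with BCL10 at 0.47 ± 0.10 and BLNK at -0.68 ± 0.12. Probe sets differed in sign for CD37 (-0.76 to 0.212) and BCL10 (-0.0623 to 0.474). Homing receptors had 3 rises and 1 fall among 16 (5 and 1 alone, median 0.60, adjusted p = 0.0546), with rises of GPR183 (1.86 ± 0.29) and CXCR5 (0.95 ± 0.19) and a fall of ITGB7 (-1.47 ± 0.24). Plasma cell genes had 2 rises and 1 fall among 17 (4 and 1 alone, median 0.15, adjusted p = 0.226), with PRDM1 and ELL2 (1.30 ± 0.30) higher and TNFRSF17 lower. Immediate early genes had 2 rises and 1 fall among 14 (3 and 1 alone, median 0.16, adjusted p = 0.114), with JUN at 2.08 ± 0.33. The cereblon list had 2 rises, CDKN1A and IKZF1, and 1 fall, MYC, among 15 (3 and 1 alone, median 0.043, adjusted p = 0.315). For glycolysis these values were 3 and 1 of 24 (median 0.13, adjusted p = 0.0906), for NF-kappaB targets 3 and 0 of 17 (0.17, 0.114), for the cell cycle 1 and 0 of 21 (-0.20, 0.315), and for cytokines and chemokines 0 and 2 of 15 (-0.10, 0.0987).

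Some lists showed little movement with both drugs. The unfolded protein response had 0 rises and 0 falls in limma among 18 (median -0.026, camera adjusted p = 0.797), oxidative phosphorylation likewise among 22 (-0.12, 0.0906) and MHC class I presentation among 13 (0.10, 0.0546). Heat shock and oxidative stress had 1 rise among 16, with a median of -0.016 whose sign differs from the mean (0.15) and from the median after median centring (0.0049), and an adjusted p of 0.750. Cytosolic ribosomal proteins had 1 fall among 20 (-0.060, 0.0551). The cytotoxic effector list had 4 measured members, too few for camera, with a median of 0.12 and SRGN at 0.52 ± 0.17. Lists of markers of other cell types had medians near 0, while 6 of their members passed, among them the bright genes LCK and VIM. Medians were 0.076 for T cells (1 of 8 fell, LCK; mean -0.13, adjusted p = 0.989) and 0.043 for NK cells (1 of 5 fell, NCR3; mean -0.13, 0.671). They were 0.16 for monocytes and macrophages (1 of 8 rose, TYROBP at 1.499 ± 0.23; 0.146) and 0.038 for platelets (0 of 5; 0.434). They were 0.016 for 4 erythroid genes, too few for camera, -0.060 for dendritic cells (FLT3 rose of 7; mean 0.21, 0.671) and 0.050 for nurse-like and stromal cells (ACTA2 rose and VIM fell of 7; mean -0.049, 0.770).

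The number of genes changed by both drugs was 329 without replicate 1, 1049 without replicate 2, 25 without replicate 3 and 40 without the replicate block. Without replicate 1 the adjusted p was 0.245 for cholesterol synthesis and 0.0502 for co-stimulation, without replicate 3 it was 0.0912 for the gamma chain list and 0.0559 for death receptors, and without the replicate block it was 0.0884 for death receptors, 0.0816 for interferon-stimulated genes and 0.0597 for ribosome biogenesis.

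Adding lenalidomide to IL-21 was examined by comparing both drugs with IL-21 alone. SUSD1 rose 11.01-fold (3.46 ± 0.39, adjusted p = 0.00349), and CDKN1A (2.88 ± 0.38, adjusted p = 0.00688), LAG3 (2.47 ± 0.42, adjusted p = 0.0159) and IL13RA1 (3.03 ± 0.49, adjusted p = 0.0146) rose strongly. CPNE5 fell to a level 8.16-fold lower (-3.03 ± 0.33, adjusted p = 0.00314), and the desaturase SCD fell (-2.06 ± 0.43, adjusted p = 0.0306), 1 of 7 falls among 15 genes of lipid synthesis. FMOD rose (2.75 ± 0.24, adjusted p = 0.00181). In all 638 genes changed, 280 upward and 358 downward, of which 94 rose and 61 fell at least 2-fold. At an unadjusted p under 0.05 there were 2627 genes, against 660 by chance. The 28S control probe sets were 1.23 ± 0.35 (SD, n = 3) and the poly-A spike-ins 0.25 ± 0.11 higher than with IL-21. The 3 prime minus 5 prime difference was higher in 3 of 3 donors for both ACTB (0.106 ± 0.0725) and GAPDH (0.0336 ± 0.013), and with the RNA quality covariate 20 genes passed, all among the 638.

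Further large rises were in DEPP1 (3.30 ± 0.41), IL4I1 (3.12 ± 0.43), GNG8 (2.97 ± 0.48), the calcineurin regulator RCAN1 (2.91 ± 0.49), SOD2 (2.59 ± 0.27), RAB13 (2.51 ± 0.27) and the nuclear receptor NR4A2 (2.45 ± 0.47). Further large falls were in KCNN3 (-2.25 ± 0.20), S100A4 (-1.93 ± 0.46), RASGRP2 (-1.89 ± 0.43), TGFBI (-1.88 ± 0.28), the kinase FGR (-1.87 ± 0.45), HLA-DOB (-1.81 ± 0.19), CRIP1 (-1.77 ± 0.14), MARCKSL1 (-1.76 ± 0.28) and PVRIG (-1.75 ± 0.25). IGHD also passed (-1.81 ± 0.27), but its 5 probe sets ranged from -1.81 to 0.15 and differed in sign. Another probe set had 1.04 for GNG8, 1.26 for RCAN1, -0.185 for RASGRP2 and -0.656 for HLA-DOB. None of the treatment genes passed. The values were 1.51 ± 0.42, adjusted p = 0.0768 for IRF4, 0.64 ± 0.21, adjusted p = 0.126 for SOCS3, 0.40 ± 0.15 for IL2RG, 0.53 ± 0.27 for IKZF1 and 0.40 ± 0.41 for IL21R. They were -0.10 ± 0.11 for CRBN, 0.21 ± 0.22 for IKZF3, 0.11 ± 0.080 for PRDM1, 0.25 ± 0.26 for STAT3 and 0.72 ± 0.39 for BCL2L11.

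Cholesterol and fatty acid synthesis had the lowest median of the tested lists, -0.64. Of 15 measured, 7 fell, 0 rose and 8 did not pass, with 10 falling when adjusted over the list alone. INSIG1 (-1.13 ± 0.19), HMGCS1 (-1.03 ± 0.21) and DHCR7 (-0.98 ± 0.23) fell together with SCD. The cholesterol list had a camera adjusted p of 6.33e-07 and adjusted p = 0.334 with an estimated correlation. In the p53 list 8 of 17 rose, 0 fell and 9 did not pass, with 10 rising when adjusted over the list alone. RPS27L (0.79 ± 0.087) and MDM2 (0.79 ± 0.15) rose besides CDKN1A, and the median was 0.63. For the p53 list camera gave an adjusted p of 7.90e-08, but adjusted p = 0.328 with an estimated correlation. Co-stimulation markers had 6 rises and 0 falls among 18, or 9 and 1 adjusted over the list alone. CD274 (1.92 ± 0.27), SLAMF1 (2.25 ± 0.34), CD70 (1.01 ± 0.17) and CD40 (0.71 ± 0.14) rose, with a median of 0.67. The co-stimulation list had a camera adjusted p of 2.97e-05 and adjusted p = 0.328 with an estimated correlation. Of 17 NF-kappaB targets, 2 rose and 0 fell, with 7 rising when adjusted over the list alone, and the subunit gene RELB rose (1.505 ± 0.28) while the median was 0.75. For the NF-kappaB list camera gave an adjusted p of 1.63e-05, but adjusted p = 0.438 with an estimated correlation. Of 12 death receptors, caspases and ligands, 3 rose (TNFRSF1A 1.37 ± 0.14, TNFRSF10B 1.02 ± 0.15, FAS 0.96 ± 0.18) and 0 fell, with 3 and 1 adjusted over the list alone and a median of 0.30. The death receptor list had a camera adjusted p of 0.0137 and adjusted p = 0.328 with an estimated correlation.

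Interferon-stimulated genes had a median of 0.78, positive in 2 of 3 donors, with 1 rise among 27 (IFIH1, 1.15 ± 0.25), 0 falls and 1 rise when adjusted over the list alone. For the interferon list camera gave an adjusted p of 5.37e-05, but adjusted p = 0.606 with an estimated correlation. IL-21 feedback genes had 1 rise among 12 (BATF, 1.18 ± 0.22), 2 adjusted over the list alone and a median of 0.32, positive in 2 of 3 donors. The IL-21 feedback list had a camera adjusted p of 0.0270 and adjusted p = 0.606 with an estimated correlation. Of 20 B cell identity genes, 2 fell (CD22 -0.71 ± 0.14, FCRL2 -1.16 ± 0.26) and 1 rose (BLK 0.55 ± 0.12), or 5 and 2 adjusted over the list alone, and the median was -0.36. For the B cell identity list camera gave an adjusted p of 0.0146, but adjusted p = 0.328 with an estimated correlation. MHC class II had 1 fall among 10 (HLA-DOB), 2 adjusted over the list alone, and a median of -0.20, negative in 2 of 3 donors. The MHC class II list had a camera adjusted p of 0.00328 and adjusted p = 0.438 with an estimated correlation. Oxidative phosphorylation had a median of -0.20 with 0 rises and 0 falls among 22 in limma, also when adjusted over the list alone. For the oxidative phosphorylation list camera gave an adjusted p of 4.43e-05, but adjusted p = 0.438 with an estimated correlation. Glycolysis had 1 fall among 24 (HK1, -0.52 ± 0.12), the same adjusted over the list alone, and a median of -0.34. The glycolysis list had a camera adjusted p of 0.00183 and adjusted p = 0.620 with an estimated correlation. Ribosome biogenesis had 0 falls over all genes and 3 adjusted over the list alone among 18, with a median of -0.19. For the ribosome biogenesis list camera gave an adjusted p of 0.0270, but adjusted p = 0.644 with an estimated correlation.

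In the cell cycle list ZWINT rose (2.18 ± 0.22), 1 of 21 and 2 when adjusted over the list alone, and the median was 0.15. The cell cycle list had a camera adjusted p of 0.0200 and adjusted p = 0.606 with an estimated correlation. Immediate early genes had 1 rise among 14 (NR4A2), 1 adjusted over the list alone, and a median of 0.36. For the immediate early list camera gave an adjusted p of 0.00328, but adjusted p = 0.438 with an estimated correlation. Dendritic cell markers had 0 rises over all genes and 3 adjusted over the list alone among 7, with 1.54 ± 0.38, adjusted p = 0.0502 for FLT3, 1.14 ± 0.34 for LILRA4 and a median of 0.22. The dendritic marker list had a camera adjusted p of 0.0146 and adjusted p = 0.328 with an estimated correlation. Of lists that did not pass, the anti-apoptotic genes CFLAR (1.45 ± 0.30) and BCL2L2 (0.53 ± 0.12) and the granule proteoglycan SRGN (0.84 ± 0.17) rose. The cytokine IL16 fell (-0.53 ± 0.10), the only call among 15 cytokines and chemokines, but had 0.016 on a probe set without shared sequence.

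The number of genes was 66 without replicate 1, 785 without replicate 2, 0 in limma without replicate 3 (1381 at an unadjusted p under 0.05) and 2 without the replicate block. Without replicate 1 the adjusted p was 0.140 for B cell identity, 0.0853 for MHC class II, 0.0827 for IL-21 feedback and 0.142 for glycolysis; without replicate 3 it was 0.204 for IL-21 feedback and 0.0685 for ribosome biogenesis, and without the replicate block 0.109 for the latter.

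**Figure D2:**
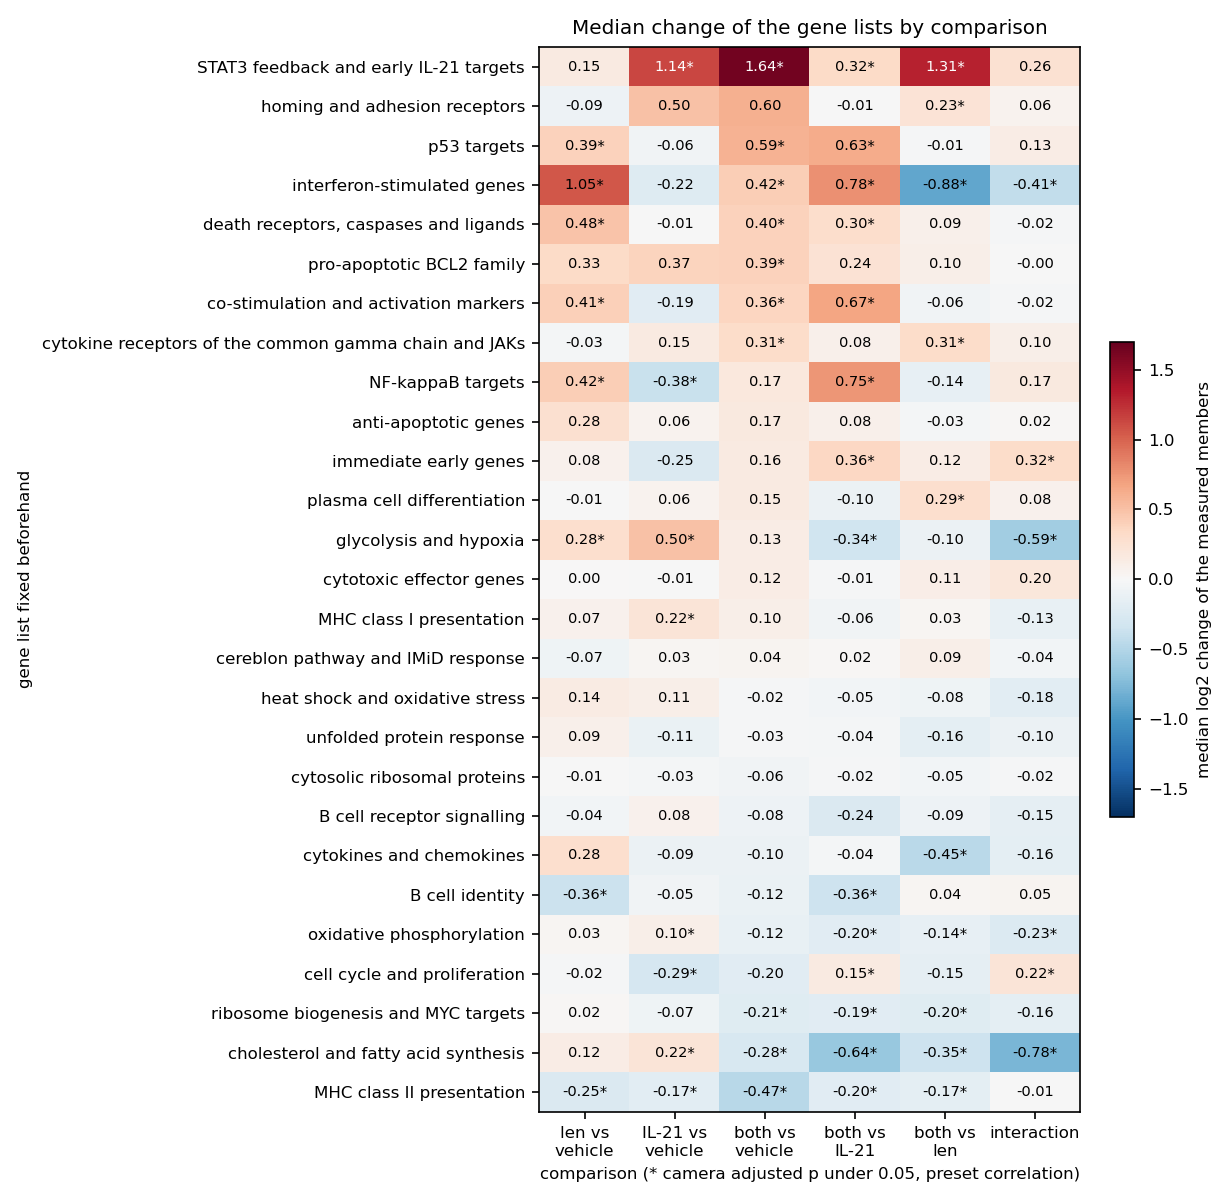
Median log2 change (colour) of the 27 gene lists other than cell type markers (vertical) in the 6 comparisons (horizontal); asterisks mark a camera adjusted p under 0.05 with the preset correlation. Cholesterol and fatty acid synthesis had a median of -0.78 in the interaction, and interferon-stimulated genes one of 1.05 with lenalidomide.

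Adding IL-21 to lenalidomide was examined by comparing both drugs with lenalidomide alone. IL2RA rose 9.35-fold (3.23 ± 0.67, adjusted p = 0.0439), and the IL-21 feedback genes SOCS3 (1.87 ± 0.21, adjusted p = 0.00630), STAT3 (1.52 ± 0.26, adjusted p = 0.0213) and BCL6 (2.54 ± 0.37, adjusted p = 0.0136) rose here too, in the presence of lenalidomide. MYO1G, a myosin of blood cells, rose with a small error (2.10 ± 0.16, adjusted p = 0.00314). CKAP2 fell to a level 6.17-fold lower (-2.62 ± 0.27, adjusted p = 0.00454), and SCD (-2.41 ± 0.43, adjusted p = 0.0245) and the estrogen receptor ESR1 (-1.52 ± 0.16, adjusted p = 0.00522) fell. In all 301 genes changed, 156 upward and 145 downward, of which 75 rose and 31 fell at least 2-fold. At an unadjusted p under 0.05 there were 2375 genes, against 660 by chance. The 28S control probe sets were 2.23 ± 0.60 (SD, n = 3) and the poly-A spike-ins 0.52 ± 0.057 higher than with lenalidomide.

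Other large rises were in FES (2.94 ± 0.62), DEPP1 (2.62 ± 0.41), SOD2 (2.36 ± 0.27), the Fc receptor FCGR2A (2.19 ± 0.40), THEMIS2 (2.12 ± 0.24), the phosphatase DUSP5 (2.10 ± 0.39), PFKFB3 (2.06 ± 0.30), GPR183 (2.03 ± 0.29) and SLC2A13 (2.02 ± 0.25). Other large falls were in PIGR (-2.00 ± 0.33), MAP2 (-1.91 ± 0.31), TNFRSF17 (-1.83 ± 0.32), the kinase NEK6 (-1.82 ± 0.29), the RNA sensor TLR7 (-1.73 ± 0.25), OAS3 (-1.51 ± 0.29), KLK2 (-1.45 ± 0.22), LCK (-1.29 ± 0.14) and B3GNT2 (-1.28 ± 0.19). Over their 3 probe sets SOCS3 had 1.87 to 6.04 and PRDM1 0.155 to 1.35. Less of a fall was found on another probe set of CKAP2 (-0.28), ESR1 (-0.0416), NEK6 (-0.163) and KLK2 (-0.262). PRDM1 rose (0.48 ± 0.080, adjusted p = 0.0207), while IL21R had 1.46 ± 0.41, adjusted p = 0.0982 and did not pass, nor did IL2RG (-0.22 ± 0.15), IRF4 (0.33 ± 0.42), IKZF1 (0.35 ± 0.27), IKZF3 (0.68 ± 0.22), CRBN (0.10 ± 0.11) or BCL2L11 (0.86 ± 0.39).

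Of 12 IL-21 feedback genes and early targets, 6 rose, 0 fell and 6 did not pass, with 10 rising when adjusted over the list alone, a median of 1.31 and SOCS1 at 1.92 ± 0.27. For the IL-21 feedback list camera gave an adjusted p of 2.16e-11, but adjusted p = 0.450 with an estimated correlation. In the gamma chain and Janus kinase list 3 of 14 rose, IL2RA, IL2RB (1.75 ± 0.26) and JAK3 (1.202 ± 0.16), 0 fell and 6 rose when adjusted over the list alone, with a median of 0.31. The gamma chain list had a camera adjusted p of 0.00165 and adjusted p = 0.450 with an estimated correlation. Interferon-stimulated genes had a median of -0.88. Of 27, 1 fell (OAS3) and 0 rose, with 8 falling and 1 rising when adjusted over the list alone, and IFIT1 had -2.60 ± 0.60, adjusted p = 0.0596. For the interferon list camera gave an adjusted p of 0.00127, but adjusted p = 0.751 with an estimated correlation. Cholesterol and fatty acid synthesis had 3 falls and 0 rises among 15, or 6 falls adjusted over the list alone. SCD, INSIG1 (-1.25 ± 0.19) and HMGCS1 (-1.002 ± 0.21) fell, and the median was -0.35. The cholesterol list had a camera adjusted p of 4.16e-05 and adjusted p = 0.602 with an estimated correlation. Of 15 cytokines and chemokines, 1 fell (LTA, -1.06 ± 0.20), 0 rose and 3 fell when adjusted over the list alone, with a median of -0.45. For the cytokine list camera gave an adjusted p of 0.00133, but adjusted p = 0.515 with an estimated correlation.

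Plasma cell genes had 2 rises, PRDM1 and the B cell coactivator POU2AF1 (1.75 ± 0.31), and 1 fall, TNFRSF17, among 17, or 3 and 1 adjusted over the list alone, with a median of 0.29. The plasma cell list had a camera adjusted p of 0.0431 and adjusted p = 0.709 with an estimated correlation. Homing and adhesion receptors had 1 rise (GPR183) and 1 fall (ITGB2, -0.997 ± 0.22, with -1.16 to 0.0307 over 3 probe sets that differ in sign) among 16, or 4 and 2 adjusted over the list alone, with 0.88 ± 0.19, adjusted p = 0.0511 for CXCR5 and a median of 0.23. For the homing receptor list camera gave an adjusted p of 0.0398, but adjusted p = 0.602 with an estimated correlation. In 3 further lists limma called 0 rises and 0 falls, also when adjusted over the list alone. MHC class II had a median of -0.17 over 10 genes, negative in 2 of 3 donors. The MHC class II list had a camera adjusted p of 0.0398 and adjusted p = 0.751 with an estimated correlation. Ribosome biogenesis had a median of -0.20 over 18 genes. For the ribosome biogenesis list camera gave an adjusted p of 0.0108, but adjusted p = 0.751 with an estimated correlation. Oxidative phosphorylation had one of -0.14 over 22 genes, negative in 2 of 3 donors. The oxidative phosphorylation list had a camera adjusted p of 0.0431 and adjusted p = 0.751 with an estimated correlation.

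The number of genes was 229 without replicate 1 and 219 without replicate 2, but limma called 0 without replicate 3 (1185 at an unadjusted p under 0.05) and 0 without the replicate block (934). Adjusted p values of lists were 0.676 without replicate 1 for MHC class II, 0.933, 0.115 and 0.115 without replicate 2 for ribosome biogenesis, homing receptors and oxidative phosphorylation. They were 0.281, 0.208, 0.0802 and 0.0802 without replicate 3 for plasma cell genes, oxidative phosphorylation, MHC class II and homing receptors. Without the replicate block they were 0.0608, 0.0608 and 0.0608 for plasma cell genes, homing receptors and oxidative phosphorylation.

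The last comparison asked whether the effect of lenalidomide differed with and without IL-21. Genes of cholesterol and fatty acid synthesis had a median interaction of -0.78, negative in 15 of 15 genes, and glycolysis and hypoxia genes one of -0.59, negative in 23 of 24. No single gene passed: limma called 0 genes, with 1139 at an unadjusted p under 0.05 (660 by chance) and a smallest adjusted p of 0.224. The 28S control probe sets had an interaction of 1.1 ± 0.42 (SD, n = 3) and the poly-A spike-ins one of 0.32 ± 0.10. The genes with the smallest p values were SLC20A1 (1.21 ± 0.18, adjusted p = 0.224), SLC18B1 (1.33 ± 0.20), INPP5A (0.83 ± 0.13), KSR1 (1.12 ± 0.17) and LOC100130987 (1.02 ± 0.17) with positive values. With negative values they were KCNN3 (-1.96 ± 0.29, adjusted p = 0.224), RHOBTB2 (-1.001 ± 0.16), LOC100129034 (-0.97 ± 0.16), CCDC24 (-1.38 ± 0.24, adjusted p = 0.270) and GALNT1 (-0.97 ± 0.18, adjusted p = 0.302). Of the treatment genes IRF4 had 1.31 ± 0.59, adjusted p = 0.580 and SOCS3 0.81 ± 0.30, adjusted p = 0.517, and none passed. IL21R had 0.24 ± 0.58, IL2RG 0.44 ± 0.21, CRBN 0.092 ± 0.15, IKZF1 -0.45 ± 0.39, IKZF3 0.42 ± 0.31, PRDM1 0.079 ± 0.11, STAT3 0.11 ± 0.36 and BCL2L11 0.28 ± 0.55.

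In the cholesterol list 9 of 15 were negative past the threshold when adjusted over the list alone and 0 over all genes, with SCD at -2.82 ± 0.61, adjusted p = 0.394, INSIG1 at -1.23 ± 0.27 and HMGCS1 at -1.21 ± 0.30. For the cholesterol list camera gave an adjusted p of 2.05e-10, but adjusted p = 0.830 with an estimated correlation. In the glycolysis list limma called 0 genes adjusted over the list alone, with ALDOC at -1.57 ± 0.42 and LDHA at -0.94 ± 0.33. The glycolysis list had a camera adjusted p of 3.34e-07 and adjusted p = 0.830 with an estimated correlation. Oxidative phosphorylation had a median of -0.23, negative in 20 of 22 genes, none of which passed in limma over all genes or adjusted over the list alone, and one of -0.0963 with the RNA quality covariate. For the oxidative phosphorylation list camera gave an adjusted p of 5.43e-05, but adjusted p = 0.830 with an estimated correlation. Interferon-stimulated genes had one of -0.41, negative in 23 of 27 genes and in 2 of 3 donors. The interferon list had a camera adjusted p of 0.0394 and adjusted p = 0.831 with an estimated correlation. Positive medians were found for the cell cycle (0.22, 2 of 21 past the threshold when adjusted over the list alone, positive in 2 of 3 donors, BUB1B at 1.198 ± 0.25; camera adjusted p = 0.0134, adjusted p = 0.831 with an estimated correlation). They were also found for immediate early genes (0.32, 2 of 14, ZFP36 at 0.97 ± 0.20; camera adjusted p = 0.0134, adjusted p = 0.830 with an estimated correlation).

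Across all genes the lenalidomide effect without IL-21 correlated with the effect in its presence (Pearson r 0.589, Spearman rho 0.395), where genes are not independent replicates and the pair of comparisons shares no array. Of the 188 genes changed by lenalidomide alone, 181 (96.3 %) had the same sign with IL-21 present, with 44 rising in both (1.7 by chance), 57 falling in both (2.93 by chance) and 0 past the threshold in opposite directions. For IL-21 without and with lenalidomide r was 0.58 and rho 0.367, 284 of 301 genes (94.4 %) had the same sign, and 55 rose and 42 fell in both (2.01 and 1.44 by chance). Counts by chance take the calls as independent between the comparisons. Both comparisons come from 1 fit with the same residual spread per gene, which can by itself raise the overlap. Adjusted p values of lists in the interaction were 0.625 without replicate 1 for the cell cycle, 0.207 without replicate 2 and 0.115 without replicate 3 for interferon-stimulated genes, 0.0519 without replicate 3 for immediate early genes, and 0.197 without the replicate block for interferon-stimulated genes.

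**Figure D3:**
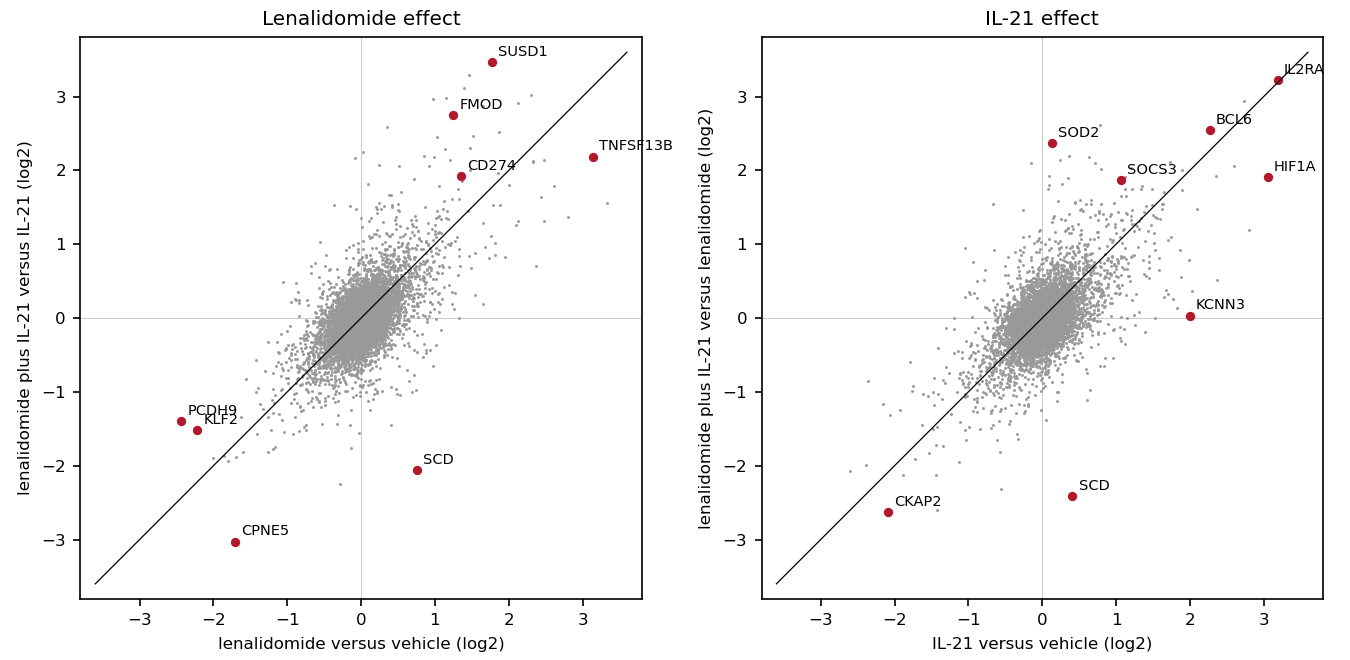
Each point is 1 of the 13195 genes; left, the log2 effect of lenalidomide without IL-21 (x axis) and with it (y axis); right, the log2 effect of IL-21 without lenalidomide (x axis) and with it (y axis), with the line of equality. The correlation across genes is 0.589 on the left and 0.58 on the right.

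The control probe sets of the arrays differed between treatments as well. The 28S probe sets had means of 9.54 ± 0.42 (SD, n = 3) with vehicle, 9.67 ± 0.41 with lenalidomide, 10.66 ± 0.60 with IL-21 and 11.89 ± 0.87 with both drugs. The 18S probe sets differed by -0.19 ± 0.31 and the hybridisation controls by 0.047 ± 0.36 between both drugs and vehicle. For 28S the exact two-sided p was 0.75 for lenalidomide versus vehicle and 0.25, the smallest that 3 donors allow, for the other 4 comparisons of treatments and for the interaction, each positive in 3 of 3 donors. The 3 prime minus 5 prime differences of ACTB and GAPDH moved in one direction in 3 of 3 donors for IL-21 versus vehicle and for both drugs versus IL-21, the 2 comparisons that lost most genes with the RNA quality covariate (301 to 14 and 638 to 20). Versus lenalidomide they moved apart (-0.0701 ± 0.0859 and 0.0353 ± 0.0235), and 493 genes passed with the covariate, 289 of them among the 301.

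**Figure D4:**
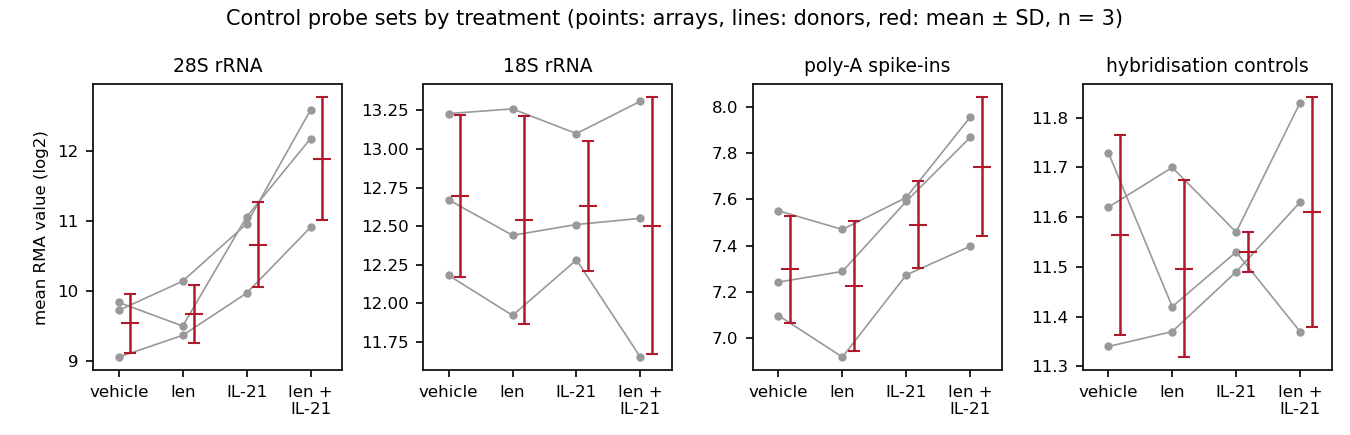
Signal of control probe sets (RMA log2 values, y axis) by treatment (x axis); points are arrays, lines join donors, and red marks give the mean ± SD (n = 3). The 28S mean is 9.54 with vehicle and 11.89 with both drugs, while the hybridisation controls differ by 0.047.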

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

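The tests of the 28S controls, of single donors and of RNA quality as explanations, and the counts of splits were chosen only after the results were seen. The interaction test, the leaving out of donors, the covariate itself and the comparison with lists matched on expression level were planned.

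In the test of the difference itself, the effect of lenalidomide differed with and without IL-21 for 6 gene lists at the preset correlation and for 0 with an estimated correlation. Camera's adjusted p was 2.05e-10 for cholesterol and fatty acid synthesis (median -0.78), 3.34e-07 for glycolysis and hypoxia (-0.59), 5.43e-05 for oxidative phosphorylation (-0.23), 0.0394 for interferon-stimulated genes (-0.41), 0.0134 for the cell cycle (0.22) and 0.0134 for immediate early genes (0.32). All 6 are lost with an estimated correlation, where the lowest adjusted p = 0.830 with an estimated correlation. Without replicate 2 the adjusted p of interferon-stimulated genes was 0.207, without replicate 1 that of the cell cycle was 0.625, and without replicate 3 that of immediate early genes was 0.0519 and that of interferon-stimulated genes 0.115.

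The negative interaction of the 3 metabolic lists means that their medians with both drugs lay below the sum of the medians' changes with each drug, not that all 3 fell. For glycolysis the median was 0.28 with lenalidomide, 0.50 with IL-21 and 0.13 with both drugs, each over vehicle. A single donor as the whole cause was argued against, since the highest adjusted p without a donor was 6.29e-08 for cholesterol synthesis, 0.0127 for glycolysis and 0.00507 for oxidative phosphorylation. So was their expression level: among 10000 random lists matched on it, the medians lay at percentiles 0, 0 and 0.02, where matched lists had medians of -0.035, -0.028 and -0.033. With the RNA quality covariate the medians were -0.74 for cholesterol synthesis and -0.63 for glycolysis (adjusted p 5.57e-09 and 6.56e-09). For these lists this argues against RNA quality as the whole cause, only as far as the ACTB and GAPDH controls measure it. For oxidative phosphorylation the median was -0.096 (adjusted p 0.0249), and RNA quality stays open. The covariate holds neither the 28S nor the poly-A spike-in controls, whose interactions were 1.1 and 0.32, positive in 3 of 3 donors. RNA differences that these controls follow were not tested and stay open for all 3 lists. No biological explanation was tested, and the calls rest on the preset correlation.

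The 28S ribosomal RNA control probe sets, which no comparison of genes used, were 1.13 higher with IL-21 and 2.36 higher with lenalidomide plus IL-21 than with vehicle, in 3 of 3 donors. Argued against as the whole cause were RNA degradation (the 3 prime minus 5 prime difference of ACTB and GAPDH changed by -0.0029, SD 0.042), hybridisation strength (the 28S rise exceeded that of the hybridisation controls by 2.31, SD 0.31) and less messenger RNA in the labelled RNA (it exceeded the poly-A spike-ins by 1.91, SD 0.58, if these were added per total RNA, which the labels do not state). So was more RNA without a poly-A tail as the whole cause, since the 28S rise exceeded that of the 18S probe sets, whose RNA lacks such a tail too, by 2.55 (SD 0.814). Such RNA as a part of the cause stays open: 20 histone genes of the replication-dependent type, whose messengers mostly lack such a tail, had a median of 0.53 and 9 other histone genes one of 0.021 (difference 0.51, one-sided permutation p = 0.00033, which takes genes as independent). The camera adjusted p of the first set was 6.71e-08, but adjusted p = 0.157 with an estimated correlation. Against it, the first set had a median of 0.31 with lenalidomide alone, where 28S differed by only 0.13. The 18S probe sets differed by -0.192 (SD 0.31), which weighs little against it so near the top of the scale. A change of the cells' ribosomal RNA, or of histone transcription in dividing cells, was not tested.

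The poly-A spike-in controls were 0.444 higher with lenalidomide plus IL-21 than with vehicle, in 3 of 3 donors. Of 4624 tested probe sets with no gene, limma called 72 for lenalidomide versus vehicle, 45 for IL-21 versus vehicle, 269 for both drugs versus vehicle, 105 versus IL-21 and 96 versus lenalidomide. Of 1235 tested probe sets with several genes, the counts in the same order were 20, 30, 159, 54 and 43.

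The 6 arrays of each comparison of treatments make 10 splits into 3 and 3, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. Only 4 of the 10 keep the pairing by parting the arrays of all 3 donors, and among these the highest other count was 0 in each comparison. In the other splits a real effect of the treatments counts as error and lowers the count, so these counts do not measure chance. The real count was 188 for lenalidomide versus vehicle (highest other 0), 301 for IL-21 versus vehicle (0), 1078 for both drugs versus vehicle (0), 638 versus IL-21 (1) and 301 versus lenalidomide (1), where the 1 comes from a split that breaks the pairing. For the interaction 100 of 100 arrangements of the treatments within donors, the real one included, gave at least the real count of 0, as any arrangement must, so this count says nothing about chance. The highest gave 1049, and so many calls in other arrangements point to a structure of the samples, the effects of the treatments themselves among them.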

How the results depend on the processing

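No alternative was added after the data had been seen. Of the counts of genes and lists under the alternatives, 94 stayed within 1.5 times the reported count and 43 did not; where no reason is given, the cause was not tested. The interaction count was 0 under each of them except the fit of 2 groups, which has no interaction. Changes near background are the least certain: genes under 5.272 were not tested, and signal near background compresses changes. Most calls depend on the replicate block and on replicate 3: of 271 named values that passed, 16 passed without the block, 5 without replicate 3, 111 without replicate 1 and 190 without replicate 2, where fewer arrays are a cause by construction.

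Without the replicate block, that is with the donor pairing left out, limma called 0 genes for lenalidomide versus vehicle, 9 for IL-21 versus vehicle, 40 for both drugs versus vehicle, 2 versus IL-21 and 0 versus lenalidomide, since the donors' differences then count as error. It also ended the list calls named with their values in the comparisons and no others. With the donor as a random effect lenalidomide versus vehicle had 91 genes. With the RNA quality covariate beside the replicate block there were 14 genes for IL-21 versus vehicle, 20 for both drugs versus IL-21 and 493 versus lenalidomide. In the first 2 the called genes kept their signs and had median absolute changes of 0.776 after 0.8 and 0.636 after 0.685, but standard errors of 0.182 after 0.137 and 0.17 after 0.129, as the covariate differs with the treatment there. The mean over probe sets gave 114 genes for lenalidomide versus vehicle. Array weights (0.37 to 3.61) gave 779 genes for lenalidomide, 1433 for IL-21 and 1932 for both drugs versus vehicle, and 1046 for both drugs versus IL-21. A fit of the 2 groups compared, with fewer arrays, gave 93, 546 and 622 genes versus vehicle and 4 for both drugs versus lenalidomide. A minimum of 2-fold, stricter by construction, gave 53, 101 and 252 genes versus vehicle, 155 versus IL-21 and 106 versus lenalidomide.

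Leaving out each donor in turn gave 0 to 215 genes for lenalidomide versus vehicle, 0 to 118 for IL-21 versus vehicle, 25 to 1049 for both drugs versus vehicle, 0 to 785 versus IL-21 and 0 to 229 versus lenalidomide. At the upper ends 87, 85, 699, 419 and 135 of these genes, in the same order, were among those called with all donors. The number of lists past the threshold ranged from 5 to 12 for IL-21 versus vehicle (8 reported), from 11 to 17 for both drugs versus vehicle (10), from 6 to 10 versus lenalidomide (10) and from 5 to 11 for the interaction (6). With an estimated correlation it was 0 in each of the 6 comparisons, against 8, 8, 10, 15, 10 and 6 with the preset one.

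Among the named values that passed, the calls lost were 70 with the donor as a random effect, 99 with RNA quality, 95 in the fit of 2 groups, 43 of 262 with the mean over probe sets, 29 with robust eBayes, 22 of 206 without probe sets of shared sequence, 20 without a filter, 8 with quantile normalisation again, 5 with array weights, 2 with median centring, 1 without the trend and 0 of 255 with the 60th percentile filter. One named value reversed, IL16 for both drugs versus IL-21, from -0.53 to 0.016 on probe sets without shared sequence, by another probe set of the gene; the other directions of named calls stayed.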

Other observations

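Gene families described here were chosen after the results were seen, 13 in number, and so was the monocyte test. Their camera p values, like that of the histone set above, are adjusted over these 13 families alone. These p values do not account for the choice, and so describe the families rather than test them. With both drugs some members of 4 families of receptors and ligands rose, while most members did not pass. Families were formed by the gene symbol alone, so that members with other symbols are left out, as CD70 and FAS are here. Of 24 interleukin receptor symbols, which take in the antagonist IL1RN, 6 rose and 0 fell, among them IL10RA (0.88 ± 0.18) and IL12RB1 (0.57 ± 0.13) besides IL13RA1 (median 0.16, camera adjusted p = 0.0142, adjusted p = 0.153 with an estimated correlation). TNF receptors with TNFRSF symbols had 5 rises and 2 falls (TNFRSF17 and TNFRSF10A) among 17, with TNFRSF8, which encodes CD30, at 0.74 ± 0.15 and the decoy receptor TNFRSF10D at 1.15 ± 0.23 (median 0.25, adjusted p = 0.0250, adjusted p = 0.157 with an estimated correlation). TNF ligands with TNFSF symbols had 3 rises and 0 falls among 7, TNFSF13B, TNFSF13, which encodes APRIL (0.90 ± 0.18), and TNFSF9 (median 0.90, adjusted p = 0.00865, adjusted p = 0.153 with an estimated correlation). Chemokine receptors had 2 rises among 10, CCR6 (1.64 ± 0.37) and CXCR5 (0.95 ± 0.19) (median 0.70, adjusted p = 0.00865, adjusted p = 0.157 with an estimated correlation). Cytosolic aminoacyl-tRNA synthetases, which charge transfer RNAs, had a median of -0.36 and 12 of 14 negative values, none past the threshold in limma (adjusted p = 0.00995, adjusted p = 0.606 with an estimated correlation).

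With lenalidomide alone all 12 of 12 KLF transcription factor genes had negative values (median -0.40, 1 fell, KLF2; camera adjusted p = 6.65e-05, adjusted p = 0.186 with an estimated correlation). With IL-21 alone the median was 0.21 with 8 of 12 positive and none past the threshold in limma (adjusted p = 0.179). With both drugs it was -0.062 with 7 negative and 2 falls, KLF2 and KLF12 (adjusted p = 0.993). Metallothioneins had positive values in 7 of 7 with lenalidomide alone, none past the threshold in limma (median 0.28, adjusted p = 0.000487, adjusted p = 0.352 with an estimated correlation). They were positive in 7 of 7 with IL-21 alone and 7 of 7 with both drugs too, and MT1F rose in both. Vacuolar ATPase subunits, which acidify lysosomes, had 1 rise among 17 with lenalidomide alone, ATP6V0E1 (0.51 ± 0.10, median 0.22, adjusted p = 0.000182, adjusted p = 0.0849 with an estimated correlation). In the interaction, mitochondrial gene families had negative values: 41 of 41 complex I genes (median -0.29, adjusted p = 2.50e-10, adjusted p = 0.274 with an estimated correlation) and 71 of 75 mitochondrial ribosomal proteins (median -0.24, adjusted p = 3.40e-11, adjusted p = 0.274 with an estimated correlation). So did 40 of 43 proteasome subunits (median -0.30, adjusted p = 3.44e-08, adjusted p = 0.274 with an estimated correlation). With the RNA quality covariate these medians were -0.143, -0.137 and -0.077, so RNA quality stays open for them. No gene of the last 3 families passed in limma, where the interaction had 1139 genes at an unadjusted p under 0.05.

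A set of 5 genes, chosen after their values were seen as better known from myeloid cells, rose with both drugs over vehicle: IL13RA1 by 3.26 ± 0.49, F13A1 by 3.08 ± 0.77, FES by 3.08 ± 0.62, FCGR2A by 2.44 ± 0.40 and TNFSF13B by 2.23 ± 0.40, to mean levels between 7.33 and 9.33. With vehicle F13A1 (4.79) and FCGR2A (4.89) lay under 5.272, where signal near background compresses changes. Monocytes or macrophages left after the B cell enrichment would bring their abundant transcripts too, but 9 of these had a median change of 0.129 (range -0.17 to 0.48) and mean levels of 3.78 to 5.65 with both drugs. Apart from CSF1R these 9 lay under 5.272 with both drugs, where changes are compressed. Levels on different probe sets cannot be compared directly. Of other monocyte markers TYROBP rose (mean 8.46 with vehicle and 9.96 with both drugs) and MS4A7 was higher (5.97 and 6.9), while MNDA had 7.66 and 7.67, FCER1G had 6.38 and 5.85, and over 21 fixed markers the median change was 0.032. The fixed monocyte and macrophage list did not pass (1 of 8 rose, camera adjusted p = 0.146). Within these limits the values argue against such cells as the whole source. Expression of these genes by the leukaemia cells themselves may account for the values, as a hypothesis that these arrays of whole cultures did not test.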
